A study of Mus musculus with 4 samples.

How the data were processed

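RNA of muscle stem cells from the hindlimb of male C57BL/6 mice aged 4 to 5 months was sequenced, with 2 control samples and 2 samples labelled conditional Hairless knockout. Per the labels' protocols, cells were sorted by flow cytometry as positive for VCAM1 and negative for CD31, CD45 and Sca1, surface proteins of endothelial cells, blood cells and fibro-adipogenic cells respectively. Total RNA was isolated, 10 ng of it was reverse transcribed with a full-length template-switching kit for low inputs, and libraries were made with an ultralow-input kit. No label says whether the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

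The authors deposited 1 table for the whole series. Per the submitters' processing notes, Trim Galore, STAR, featureCounts from Subread and edgeR were used, and the genome build was mm10, also called GRCm38. Their versions and settings are not given in the sources used here. Per the file headers, each row is an Entrez gene with the coordinates of its exons and a summed exon length, as featureCounts writes them. The unit of the 4 per-sample columns is not in the header. The values behaved as RPKM (reads scaled by gene length and library size) computed by the authors, because each value times the gene length was a whole multiple of 1 step per column. With a tolerance of 0.01 reads, 100% of the values in every library came out as whole reads. Columns that begin with Ct were matched to the control samples and columns that begin with Fl to the knockout samples, with the replicate number in the column name. The labels do not spell out Fl, so this match rests on Ct naming the control columns. The table also holds a q-value per gene for the authors' deposited comparison of knockout with control. The model behind it and the filter that left 11603 genes are not given in the sources used here.

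The recovered reads summed to 26990809 and 22577330 in control 1 and control 2 and to 34101213 and 21757211 in knockout 1 and knockout 2. The library sizes by which the authors divided were 85.9%, 92.4%, 75.7% and 75.5% of these sums, in the same order. Scaling by the reads listed would therefore move the median log2 fold change of all genes by -0.20, and changes are reported on the authors' scale. The spread between replicates, which includes counting error, sets the precision of each value.

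The design written before the data were examined assumed raw counts and a count model. Because the deposited values are RPKM, the main test was limma with a mean-variance trend on log2(RPKM + 0.5), over all 11603 genes and 4 libraries with genotype as the only term, and Benjamini-Hochberg adjustment with a threshold of 0.05. Log2 fold changes are on this log2(RPKM + 0.5) scale, which understates the change of genes with low values, and values given as N-fold are ratios of the group means in RPKM. limma version 3.58.1 was run in R 4.3.3. Groups of genes were tested with camera from limma, with a preset correlation of 0.01 between genes, for the 24 of 26 lists with at least 5 measured members, adjusted over the 24 lists. The lists and their members were written before the data were examined. Each list test was repeated with a correlation estimated from the list, and fry was run beside it. List members were matched by symbol, or through the Entrez ID and synonyms of the RefSeq table of GRCm38.p6, in which 11594 of the 11603 Entrez IDs were found. Of 17 Entrez IDs on more than 1 row, the row with the highest mean was used. In the deposited table, 17 symbols had been turned into dates, and these rows were tested but not named.

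Genes were named by a rule set before the data were examined. It names Hr first, then in each direction the 10 genes with the largest log2 change among those past the threshold with at least 5 CPM (reads scaled by library size, RPKM times length) over the 4 libraries and with both knockout values beyond both control values. Unnamed gene models were left out, and genes with the smallest p fill the 10 as values. For each list it names the members past the threshold, at most 4, or the 2 members with the highest mean CPM where none passes. Other genes in the text were chosen after their values were seen, mostly as the members of a list with the smallest p.

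The fit, the list test and the recovery of reads were checked on simulated data for knockout against control with 2 libraries each and 11603 genes, of which 200 were changed and a list of 40 more was lowered by a set amount. limma called 86% of the genes changed 2-fold and 100% of those changed 4-fold, 8-fold or 16-fold, with 2 calls among 11363 unchanged genes. The simulation used 1 dispersion for all genes and independent libraries, and it changed no genes with few reads. Its shares therefore do not carry over to these libraries, where Actc1, 10.9-fold lower in knockout, had a limma adjusted p of 0.126. A gene that limma did not call may still have changed by several fold. Alternatives were other pseudocounts, filters and scalings, limma-voom on the recovered reads, a term for the replicate number and leaving out each library. Reads from genes with near-identical copies, such as actins, alpha tubulins and ribosomal protein genes, may have been split or dropped in the authors' counting, so their levels are uncertain. No label or header says that counting used strand, so overlapping genes on opposite strands cannot be told apart.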

Results

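Gene expression was measured by RNA sequencing in muscle stem cells, the resident Pax7-expressing precursors of skeletal muscle, sorted from the hindlimb of mice. There were 2 control libraries and 2 libraries labelled as a conditional knockout of Hairless (Hr), which encodes a nuclear corepressor. The series title names heterochromatin maintenance and antagonism of a histone demethylase as the subject. The comparison of knockout with control asks which transcripts depend on Hr in these cells. The libraries held 21757211 to 34101213 reads on the 11603 genes listed. Values are RPKM, with n = 2 per group, and library values are given as control 1 and control 2, then knockout 1 and knockout 2.

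Hr (Entrez gene 15460, chromosome 14, 70552212 to 70573548, plus strand, mm10) had 9.28 and 8.94 RPKM in the control libraries and 7.15 and 7.90 RPKM in the libraries labelled knockout. The means were 9.11 ± 0.241 and 7.53 ± 0.528 (SD, n = 2), a log2 fold change of -0.26 with a standard error of 0.16 and a limma adjusted p of 0.431. Both knockout values lay below both control values, but the transcript was not lost and the difference did not pass the test. Values are summed over all exons of the gene, so they cannot show whether a part of it was deleted. The direction of every difference below therefore rests on the sample labels.

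In the knockout libraries, lists of myofibre, cell cycle and extracellular matrix genes were lower than other genes, and lists of interferon-stimulated, immediate-early and ribosomal protein genes were higher. These and 5 weaker list calls, 11 of 24 in all, rested on a preset correlation between genes and had an adjusted p of 0.609 with an estimated correlation. That alternative works with 2 residual degrees of freedom. It gave the same 0.609 to lists with estimated correlations from 0.0159 to 0.795, so it had little power to call any list. The 0.609 repeated below therefore does not show that correlation between the genes accounts for a call. After adjustment over all genes, limma called 1 gene lower, Col1a1, and 0 genes higher. At an unadjusted p under 0.05 limma counted 1191 genes higher and 892 lower, where chance gives 580.15 in all. With limma-voom on the recovered reads 3 genes were called higher and 8 lower. In the authors' deposited table, 910 genes had an adjusted p under 0.05, 416 higher and 494 lower in the knockout. Of these 910 genes, 901 had both knockout values beyond both control values and 852 had an unadjusted limma p under 0.05. Such a separation was seen in 5938 of all 11603 genes (51.2%), where chance gives 33.3%. Across genes, which are not independent replicates, the authors' adjusted p and the limma p ranked genes with a Spearman correlation of 0.956.

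Col1a1, the main chain of type I collagen (Entrez gene 12842, chromosome 11, 94936224 to 94953042), fell from 70.2 ± 4.57 to 12.6 ± 0.106 RPKM (SD, n = 2). This was a log2 fold change of -2.43 with a standard error of 0.14 and a limma adjusted p of 0.0385. The gene was lower in both knockout libraries than in either control library. The call did not hold when any of the 4 libraries was left out, with adjusted p values of 0.0805 without control 1, 0.411 without control 2, 0.073 without knockout 1 and 0.0619 without knockout 2, while the log2 fold change stayed between -2.50 and -2.37.

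The other 9 genes given for the lower direction had a limma adjusted p of 0.126 and are reported as values. Myogenin (Myog, chromosome 1, 134289989 to 134292548), the transcription factor of terminal myogenic differentiation, had 111 and 188 RPKM in control and 23.7 and 28.1 RPKM in knockout, a log2 fold change of -2.46 with a standard error of 0.27. Tmem8c (Myomaker), the membrane protein required for myoblast fusion, had 27.1 and 41.5 RPKM against 5.02 and 6.00 RPKM. Actc1, the cardiac actin also made by differentiating myoblasts, showed the largest change among the genes given, from 80.9 ± 29.6 to 7.41 ± 2.56 RPKM (SD, n = 2), 10.9-fold lower. Klhl41, a sarcomere-associated protein, had 5.13 and 8.49 RPKM against 1.03 and 0.818 RPKM. Fndc5, the precursor of irisin, had 4.73 and 7.01 RPKM against 0.953 and 1.15 RPKM. Cdkn1c, which encodes the cyclin-dependent kinase inhibitor p57, had 340 and 552 RPKM against 80.0 and 95.05 RPKM. Dlk1, an imprinted membrane protein, had 5.75 and 4.67 RPKM against 1.27 and 1.36 RPKM. The matrix genes Tnc (tenascin C) and Col26a1 were 5.41-fold and 6.77-fold lower in the knockout mean. Each of these 9 genes had an adjusted p under 0.05 in the authors' deposited table, from 1.91e-07 for Cdkn1c to 8.95e-19 for Actc1.

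**Figure D1:**
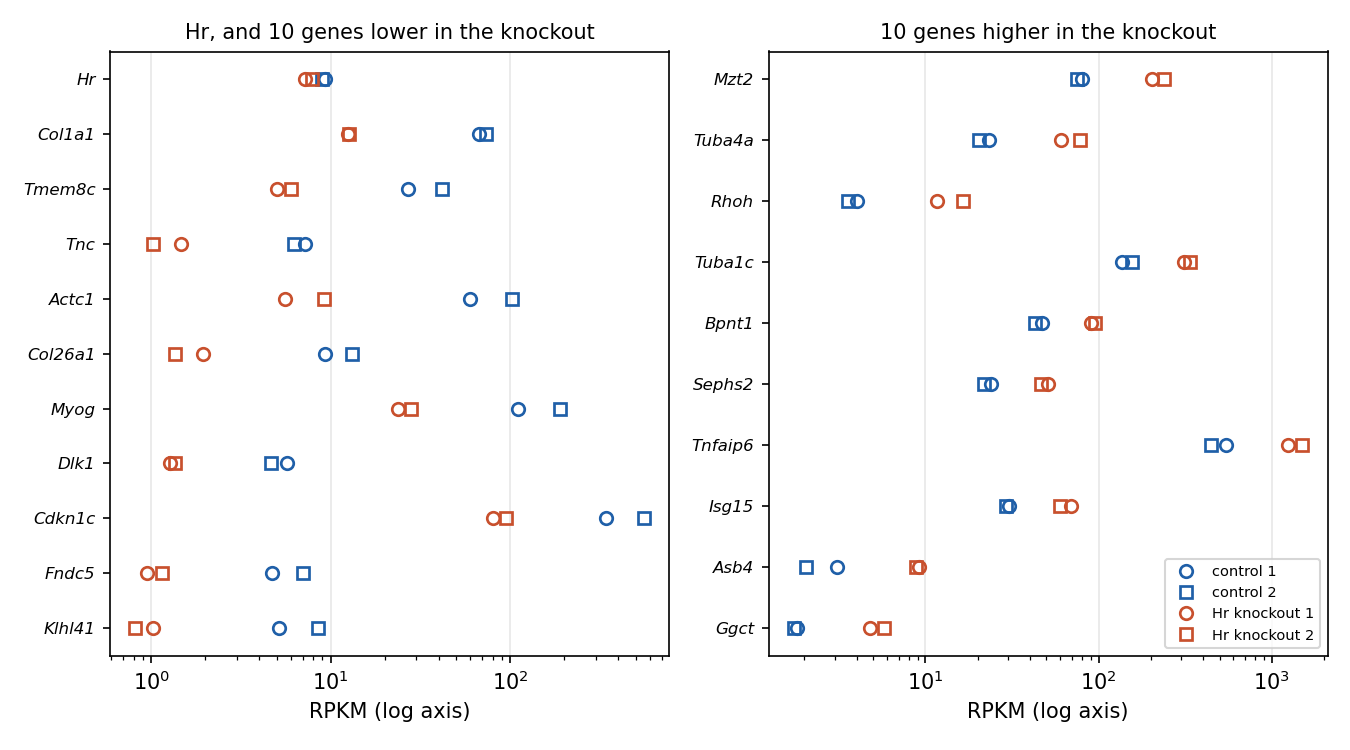
RPKM per library on a log axis for Hr and the 10 genes given in each direction. Blue marks are the control libraries and orange marks the knockout libraries (circle, library 1, square, library 2). Hr lies at 7.15 to 9.28 RPKM in all 4 libraries. Only Col1a1, at 67.0 and 73.4 RPKM in control and 12.5 and 12.6 RPKM in knockout, passed the limma threshold.

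The 10 genes given for the higher direction had limma adjusted p values of 0.126 to 0.133, so none passed the test, and both knockout values exceeded both control values in each of them by the rule of choice. Among them were the tubulin-related genes Tuba4a, an alpha tubulin (23.3 and 20.3 RPKM in control, 60.7 and 78.3 RPKM in knockout), Tuba1c, another alpha tubulin (137 and 155 RPKM, 312 and 338 RPKM), and Mzt2, a component of the gamma-tubulin complex (79.7 and 75.4 RPKM, 204 and 239 RPKM). Tnfaip6, a secreted hyaluronan-binding protein, had 548 and 447 RPKM against 1249 and 1499 RPKM, and Isg15, an interferon-induced ubiquitin-like protein, had 30.5 and 29.3 RPKM against 69.0 and 59.6 RPKM. Rhoh, Asb4, Ggct, Sephs2 and Bpnt1 were 3.71-fold, 3.51-fold, 2.97-fold, 2.13-fold and 2.06-fold higher in the knockout mean. Of the 10 genes, Isg15 was the only one that did not have an adjusted p under 0.05 in the authors' deposited table, where its value was 0.0934.

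Genes of quiescence and stem cell identity did not move together. Of 32 measured members 0 passed limma over all genes, and 5 were higher and 5 lower when adjusted over the list alone. In the authors' deposited table, 4 members were higher and 5 lower. The 2 most abundant members were Gpx3, a secreted glutathione peroxidase (5887 and 5044 RPKM in control, 9157 and 9841 RPKM in knockout), and Sdc4, the surface proteoglycan syndecan 4 (2121 and 1582 RPKM, 3031 and 3260 RPKM). Members chosen after their values were seen went the other way, such as the imprinted noncoding RNA Meg3 (43.8 and 33.8 RPKM, 18.9 and 15.4 RPKM) and Itga7, the alpha 7 integrin of muscle (90.8 and 118 RPKM, 61.9 and 49.9985 RPKM). Pax7 had a log2 fold change of 0.07 with a limma adjusted p of 0.951 over the list alone. The list median was -0.02, with a camera adjusted p of 0.805. Notch pathway genes had a median of 0.03 over 22 measured members and a camera adjusted p of 0.933, with 0 members past the threshold over all genes and 0 when adjusted over the list alone. Its 2 most abundant members were the target gene Heyl (70.3 and 112 RPKM, 80.4 and 135 RPKM) and the receptor Notch3 (24.9 and 26.9 RPKM, 25.7 and 25.6 RPKM).

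Genes of activation and commitment went in both directions. Adjusted over the list alone, 5 of its 23 measured members were lower and 1 was higher, with 0 over all genes. In the authors' deposited table, 5 were lower and 1 higher. Members chosen after their values were seen were Myod1, the determination factor, which had 977 and 694 RPKM in control and 1711 and 1413 RPKM in knockout, and Ccnd1, encoding cyclin D1, which had 17.9 and 22.9 RPKM against 10.2 and 7.37 RPKM. Chrna1, a subunit of the muscle acetylcholine receptor, had 33.0 and 46.5 RPKM against 18.2 and 19.2 RPKM. The 2 most abundant members were Myc (720 and 722 RPKM, 992 and 1006 RPKM) and Des, encoding desmin (538 and 489 RPKM, 715 and 655 RPKM). The list as a whole had a camera adjusted p of 0.135.

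Myofibre and terminal differentiation genes were lower as a group, with a median log2 fold change of -0.84 over 25 measured members and a camera adjusted p of 2.83e-07. With an estimated correlation between its genes the adjusted p was 0.609. Of the 25 members 0 passed limma over all genes and 2, Actc1 and Acta1, were lower when adjusted over the list alone, while the authors' deposited table had 15 lower and 0 higher. Acta1, the skeletal alpha actin, had 144 and 455 RPKM in control and 36.5 and 31.9 RPKM in knockout. Tpm1, a tropomyosin and the other of the 2 most abundant members, had 16.6 and 38.0 RPKM against 15.5 and 19.3 RPKM. Some genes of adult fast fibres, chosen after their values were seen, stood high in control 2 alone, and others such as Ryr1 (0.923 and 1.17 RPKM in control, 0.935 and 1.26 RPKM in knockout) did not. Pvalb, encoding the calcium buffer parvalbumin, had 5.22 and 54.4 RPKM in control and 3.53 and 3.68 RPKM in knockout, and Ckm, the muscle creatine kinase, had 3.63 and 39.4 RPKM in control and 3.39 and 2.93 RPKM in knockout. Without control 2 the list median was -0.40, and without control 1 it was -1.36. With the correlation of 0.678 estimated between these genes, the -0.40 had a standard error of 0.79, so it decides nothing for the list.

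Cell cycle genes were lower as a group, with a median log2 fold change of -0.60 over 36 measured members and a camera adjusted p of 7.88e-09, or an adjusted p of 0.609 with an estimated correlation. Adjusted over the list alone 21 members were lower and 4 higher, against 0 over all genes, and the authors' deposited table had 20 lower and 3 higher. The members with the smallest p, chosen after their values were seen, act in mitosis or DNA topology and were low in every library. Ccnb2, encoding cyclin B2, had 4.09 and 7.09 RPKM in control and 1.06 and 0.711 RPKM in knockout. Aurkb, the Aurora B kinase, had 1.11 and 2.21 RPKM against 0.105 and 0.0413 RPKM, Top2a (topoisomerase II alpha) had 1.17 and 1.96 RPKM against 0.228 and 0.216 RPKM, and the proliferation marker Mki67 had 0.976 and 1.98 RPKM against 0.142 and 0.157 RPKM. The 2 most abundant members went the opposite way. Pcna, the sliding clamp of DNA polymerase, had 72.5 and 61.7 RPKM against 116.3 and 116.0 RPKM, and Rrm2, a ribonucleotide reductase subunit, had 35.9 and 20.5 RPKM against 60.5 and 47.4 RPKM.

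**Figure D2:**
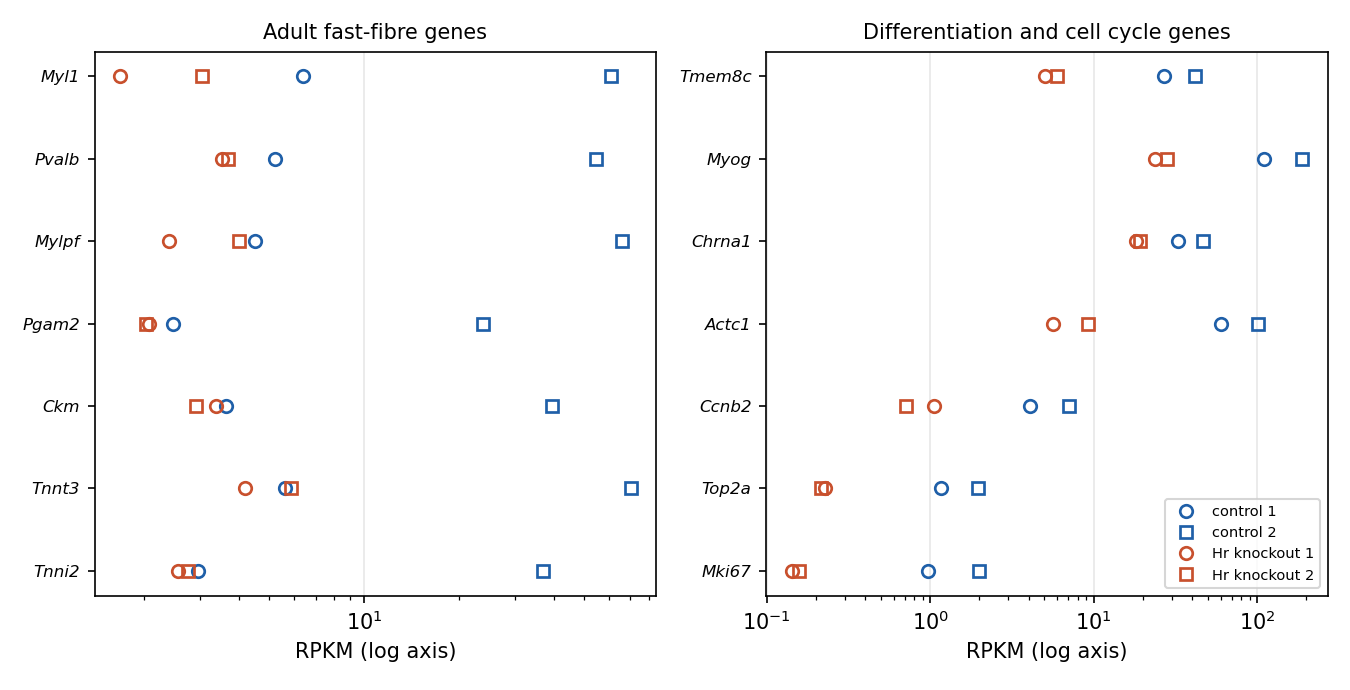
RPKM per library on a log axis for 7 adult fast-fibre genes (left) and 7 genes of differentiation and the cell cycle (right), all chosen after their values were seen. Blue marks are control and orange marks knockout libraries (circle, library 1, square, library 2). On the left control 2 stands far above the other libraries, as for Pvalb with 54.4 RPKM against 5.22 RPKM in control 1. There control 1 also lies above both knockout libraries in all genes but Tnnt3, most clearly for Myl1 with 6.38 RPKM against 1.68 and 3.05 RPKM. On the right both control libraries lie above both knockout libraries, as for Myog with 111 and 188 RPKM against 23.7 and 28.1 RPKM.

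Lists of p53 targets and of DNA repair were lower by small amounts. The p53 target list had a median of -0.27 over 38 measured members and a camera adjusted p of 0.0151, and the DNA damage repair and checkpoint list had a median of -0.14 over 47 members and a camera adjusted p of 0.0171. Each had an adjusted p of 0.609 with an estimated correlation. Without control 2 the adjusted p values became 0.0506 and 0.0798, and without knockout 1 they became 0.0849 and 0.119. Without control 1 the DNA repair median was -0.22. Scaling by the reads listed moved the median over all genes by -0.20. It gave medians of -0.41 for p53 targets and -0.31 for DNA repair, with camera adjusted p values of 0.0953 and 0.108. Neither call held. Over all genes 0 members of either list passed limma. Adjusted over the list alone 2 p53 list members were lower, Psrc1 (2.82 and 3.99 RPKM in control, 0.288 and 0.832 RPKM in knockout) and Gtse1 (0.729 and 1.27 RPKM, 0.157 and 0.0447 RPKM), both of which act on the mitotic spindle or in G2 phase, and limma called 0 DNA repair genes. The authors' deposited table had 2 members higher and 5 lower on the p53 target list, and 2 higher and 6 lower on the DNA repair list. The 2 most abundant p53 targets were Cdkn1a, encoding p21 (950 and 1144 RPKM, 1171 and 1689 RPKM), and the antiproliferative gene Btg2 (279 and 389 RPKM, 432 and 941 RPKM). H2afx, the histone variant that is phosphorylated at DNA breaks, had 54.2 and 47.9 RPKM against 76.3 and 98.7 RPKM, and Rif1, a factor of break repair and replication timing, had 5.66 and 6.50 RPKM against 4.62 and 5.20 RPKM. Senescence and secretory genes had a camera adjusted p of 0.825 over 32 members, with 0 called by limma over all genes or adjusted over the list alone, while the authors' deposited table had 1 higher and 3 lower. The chemokine gene Cxcl1 had 1502 and 1044 RPKM against 1975 and 2148 RPKM, and the metalloproteinase inhibitor gene Timp2 had 202 and 215 RPKM against 188 and 165 RPKM.

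Machinery of H3K9 methylation and heterochromatin, the subject named in the series title, had a median of -0.16 over 46 measured members and a camera adjusted p of 0.0346, or an adjusted p of 0.609 with an estimated correlation. The call was also lost without control 1, at 0.0668, and without knockout 2, at 0.119. The median was -0.10 without control 2. When libraries were scaled by the reads listed, which moved the median over all genes by -0.20, it was -0.39. None of its members passed limma over all genes or when adjusted over the list alone, and the authors' deposited table had 3 lower and 0 higher. Those 3, chosen after their values were seen, were Uhrf1, which maintains DNA methylation at replication (1.45 and 2.27 RPKM in control, 0.664 and 0.457 RPKM in knockout), Lmnb2, encoding lamin B2 (11.6 and 17.7 RPKM, 7.74 and 6.14 RPKM), and Hells, a chromatin remodeller (0.299 and 0.379 RPKM, 0.156 and 0.0591 RPKM). The most abundant members, Lmna, encoding lamin A, and the putative demethylase gene Jmjd1c, had log2 fold changes of 0.01 and 0.21. Nuclear receptors and corepressor partners had a camera adjusted p of 0.656 over 22 members and 0 limma calls over all genes, and 2 members were higher in the authors' deposited table. For this list fry gave an adjusted p of 0.0004 for change in either direction and a directional adjusted p of 0.296. Dio3, the deiodinase that inactivates thyroid hormone, was the 1 member called higher when adjusted over the list alone, with 0.765 and 0.425 RPKM in control and 3.59 and 2.34 RPKM in knockout. The hormone-responsive factor Klf9 had 318 and 314 RPKM against 379.1 and 379.2 RPKM, and the orphan receptor gene Rora had 23.6 and 24.9 RPKM against 35.0 and 37.9 RPKM.

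Canonical histone genes had a camera adjusted p of 0.424 over 11 measured members, 0 limma calls over all genes, 2 lower when adjusted over the list alone and 1 lower in the authors' deposited table. Hist1h1c had 27.6 and 50.2 RPKM in control against 17.1 and 38.9 RPKM in knockout, and Hist1h2bc had 66.3 and 71.0 RPKM against 59.6 and 86.1 RPKM. Of 32 germline genes 2 were measured and the list was not tested. Brdt had 1.37 and 1.07 RPKM against 1.29 and 1.21 RPKM, and Piwil4 stayed at or below 0.0712 RPKM in every library.

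Extracellular matrix and adhesion genes were lower as a group, with a median log2 fold change of -0.48 over 39 measured members and a camera adjusted p of 5.31e-11, or an adjusted p of 0.609 with an estimated correlation. Col1a1 was the member that fell over all genes. Adjusted over the list alone 15 were lower and 0 higher, and the authors' deposited table had 10 lower and 0 higher. Other members, chosen after their values were seen, were Col1a2, the second chain of type I collagen (22.6 and 39.4 RPKM in control, 4.02 and 6.56 RPKM in knockout), Lamb1, the laminin beta 1 chain (10.1 and 9.47 RPKM, 3.19 and 1.96 RPKM), and Col6a2 (21.4 and 22.7 RPKM, 12.9 and 11.3 RPKM). Some matrix genes are also markers of other cell types followed below, among them Col1a1, Col3a1 and Fbn1 of the fibro-adipogenic list, in which 4 markers were lower when adjusted over the list alone, and Tnc of the tenocyte list. The tenocyte median was -0.51, but -0.012 without control 1, 0.0394 without knockout 1, -0.93 without control 2 and -1.03 without knockout 2. Wnt pathway genes had a median of 0.18 over 19 measured members and a camera adjusted p of 0.0346, or an adjusted p of 0.609 with an estimated correlation. That call was lost without control 2, at 0.13, and without knockout 1, at 0.073. The Wnt median was 0.32 without control 1. It was 0.0279 when libraries were scaled by the reads listed, which moved the median over all genes by -0.20. The 2 members that were higher in the authors' deposited table were the ligand Wnt4 (7.36 and 8.57 RPKM, 14.0 and 23.99 RPKM) and the secreted antagonist Sfrp4 (6.9993 and 5.27 RPKM, 12.0 and 10.1 RPKM), and limma called 0 members over all genes or adjusted over the list alone. The abundant members Ctnnb1, encoding beta-catenin, and the receptor gene Lrp6 had log2 fold changes of 0.06 and 0.25.

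Interferon-stimulated genes were higher as a group, with a median of 0.45 over 34 measured members and a camera adjusted p of 1.84e-07, or an adjusted p of 0.609 with an estimated correlation. Adjusted over the list alone 8 members were higher and 0 lower, with 0 over all genes, and the authors' deposited table had 4 higher. Among members chosen after their values were seen, the transcription factor gene Irf7 had 6.77 and 7.33 RPKM in control and 19.9 and 15.0 RPKM in knockout, and the antiviral gene Mx2 had 1.83 and 2.07 RPKM against 5.22 and 4.65 RPKM. The most abundant members were Ifi27 (154 and 127 RPKM, 280.0 and 212 RPKM) and Gbp2 (67.5 and 32.2 RPKM, 106 and 51.7 RPKM). Without knockout 1 the list median was 0.22 and the camera adjusted p was 0.0202, and without knockout 2 the median was 0.77. Knockout 1 was also the library with the most Cd74, the invariant chain that associates with MHC class II (10.1, 14.5, 98.9 and 16.7 RPKM). The immediate-early and dissociation response list had a median of 0.53 over 41 measured members and a camera adjusted p of 4.29e-10, or an adjusted p of 0.609 with an estimated correlation. None of its members passed limma over all genes or when adjusted over the list alone, and the authors' deposited table had 7 higher and 0 lower. Egr1 had 1515 and 2289 RPKM in control and 2097 and 3384 RPKM in knockout, so its groups overlapped, and the chaperone gene Hsp90aa1 had 946 and 650 RPKM against 1411 and 1287 RPKM. The median of this list was 0.35 without knockout 2. Scaling by the reads listed moved the median over all genes by -0.20. With it the interferon median was 0.24 and the immediate-early median 0.29.

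Cytosolic ribosomal protein genes had a median of 0.47 over 47 measured members, with quartiles of 0.41 and 0.53 and a camera adjusted p of 6.94e-17. With an estimated correlation, which was 0.795 between these genes, the adjusted p was 0.609. Both knockout values lay above both control values in 46 of the 47 genes, where chance gives 16.7% in 1 direction for a single gene. Genes so correlated are not independent draws, and 51.2% of all genes separated in either direction. Of the 47 genes 0 passed limma over all genes or adjusted over the list alone, and 0 were called in the authors' deposited table. Rplp0 had 1291 and 1121 RPKM against 1586 and 1735 RPKM, and Rpl4 had 1453 and 1312 RPKM against 1891 and 2029 RPKM. Nuclear-encoded respiratory chain genes had a median of 0.16 over 47 measured members and a camera adjusted p of 0.000371, or an adjusted p of 0.609 with an estimated correlation, with 0 called by limma over all genes, over the list alone or in the authors' deposited table. When libraries were scaled by the reads listed, which moved the median over all genes by -0.20, the ribosomal median became 0.23 and the respiratory chain median -0.07. Without knockout 2 the respiratory chain median was 0.0914. The ATP synthase genes Atp5b and Atp5a1 had log2 fold changes of 0.01 and -0.01. Short genes tended to have higher values in knockout libraries. The median log2 fold change was 0.32 in the 325 genes of over 500 and up to 1000 bases and -0.11 in the 1664 genes above 8000 bases. Across genes, log2 fold change and length had a Spearman correlation of -0.295. Only the ribosomal protein and respiratory chain lists were compared with lists matched on length, so the part of this trend in other list medians was not tested. Mitochondrially encoded genes had a camera adjusted p of 0.656 over 8 measured members, with COX1 at 2777 and 2572 RPKM against 2116 and 2202 RPKM and CYTB at 4484 and 3937 RPKM against 3525 and 3632 RPKM.

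**Figure D3:**
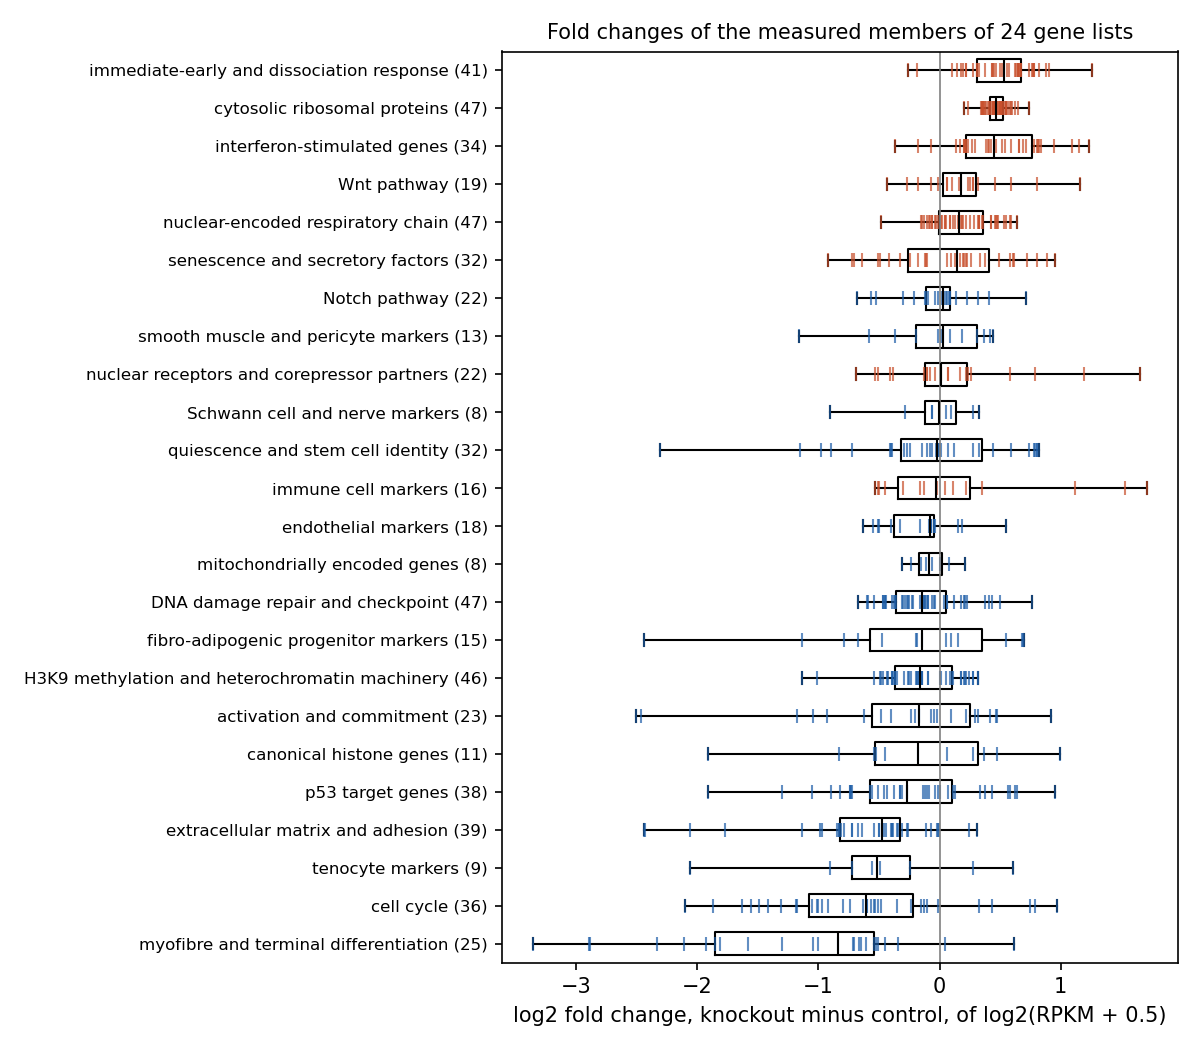
Log2 fold changes (knockout minus control, of log2(RPKM + 0.5)) of the measured members of the 24 gene lists tested, with the number of members in brackets. Each tick is a gene, orange where the list mean is above 0 and blue where it is not. Boxes span the quartiles, the black line is the median and whiskers reach the extremes. Medians run from -0.84 for myofibre genes to 0.53 for immediate-early genes.

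Markers of other cell types that the sort could have retained were followed in the same way, and camera called none of these lists. The adjusted p was 0.459 for 18 endothelial markers, 0.936 for 16 immune markers, 0.424 for 15 fibro-adipogenic markers, 0.956 for 13 smooth muscle and pericyte markers, 0.956 for 8 Schwann cell markers and 0.135 for 9 tenocyte markers. Without knockout 2 the endothelial, Schwann cell and tenocyte lists were called lower, with adjusted p values of 2.92e-05, 0.0206 and 0.000735. Without knockout 1 the endothelial and Schwann cell lists turned the other way, with medians of 0.18 and 0.31 and adjusted p values of 0.0849 and 0.11, and the tenocyte list had an adjusted p of 0.861. Without control 2 the fibro-adipogenic and tenocyte lists were called lower, at 0.0445 and 0.0034, while without control 1 the fibro-adipogenic list had a median of 0.23 and an adjusted p of 0.877. Over all genes Col1a1, which is on the fibro-adipogenic list, was the only marker that passed. Adjusted over the list alone 2 fibro-adipogenic markers were higher and 4 lower, and 1 tenocyte marker, Tnc, was lower. The authors' deposited table had 2 immune markers higher, and 4 fibro-adipogenic, 1 smooth muscle and 1 tenocyte marker lower. Ly6a, which encodes the Sca1 antigen used to exclude cells, had 47.9 and 49.5 RPKM in control and 77.4 and 80.7 RPKM in knockout.

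Levels of the abundant markers differed between single libraries. The endothelial markers Fabp4 (47.3 and 51.4 RPKM in control, 39.1 and 76.9 RPKM in knockout) and Plvap (49.97 and 56.2 RPKM, 44.9 and 58.6 RPKM) overlapped between groups. Cd14, a monocyte marker, had 19.04 and 12.6 RPKM against 16.1 and 24.6 RPKM. Acta2, the smooth muscle actin, had 321 and 474 RPKM against 148 and 205 RPKM with a limma adjusted p of 0.168. The nerve markers Pmp22 (194 and 181 RPKM, 219 and 253 RPKM) and Egr2 (86.6 and 110 RPKM, 96.2 and 145 RPKM) and the tendon markers Thbs4 (32.9 and 16.2 RPKM, 10.9 and 23.6 RPKM) and Fmod (29.1 and 13.9 RPKM, 9.63 and 20.7 RPKM) did not pass. Haemoglobin transcripts were highest in knockout 2, with Hba-a2 at 20.4 and 15.8 RPKM in control and 4.10 and 66.0 RPKM in knockout and Hbb-bs at 15.5 and 12.0 RPKM against 4.35 and 58.8 RPKM. These were the 2 measured genes of the erythroid list, which was not tested. fry, which asks only whether a list's own genes move, gave directional adjusted p values of 0.217 to 0.375 for the 11 lists called by camera, and 0.0236 to 0.153 for change in either direction. Some lists that camera did not call also had small fry adjusted p values for change in either direction. These were 0.0004 for nuclear receptors and corepressor partners, 0.00555 for fibro-adipogenic markers and 0.045 for quiescence and stem cell identity.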

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

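The pseudocounts, the filters and the scalings left the call of Col1a1 as the only one. Both the planned pseudocounts of 0.1 and 1 and all 3 filters gave 0 genes higher and 1 lower, as did scaling by median of ratios or by reads listed. Counts moved with the model. limma-voom on the recovered reads called 3 genes higher and 8 lower. Adding the replicate number as a term (replicate block) called 591 genes higher and 413 lower. The deviations of libraries with the same number correlated at 0.39 across genes, but there were only 2 pairs. No label says that a number marks a shared animal or day, so whether these libraries share more than a number is not known. The fit with this term also has fewer residual degrees of freedom than the main fit. At an adjusted p under 0.01 the count of lower genes was 0. Leaving out 1 library gave 0 to 1 genes higher and 0 lower, with the lone library of a group assumed to vary like the other group. The cause of these differences was not tested. The log2 fold change of Hr stayed between -0.48 and -0.19 and was not called under any alternative run. The count models planned for raw counts (the DESeq2 Wald test and the edgeR likelihood ratio and exact tests, and the edgeR quasi-likelihood test with its expression filter) were not run, because the authors deposited RPKM.

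Each of the 11 lists called by camera was lost when the correlation was estimated per list, with an adjusted p of 0.609 for myofibre, cell cycle, p53 target, DNA repair, H3K9 and heterochromatin, extracellular matrix, Wnt, interferon-stimulated, immediate-early, ribosomal protein and respiratory chain genes. That alternative works with 2 residual degrees of freedom, and the H3K9 and heterochromatin list was lost with an estimated correlation of only 0.0159. The replicate block, median-of-ratios scaling, limma-voom and both pseudocounts kept all 11 calls. Scaling by reads listed, added for lists after seeing the data like the pseudocounts, the voom values and the filter on mean RPKM, gave 0.108 for DNA repair and 0.0953 for p53 targets. The filter on a mean of at least 1 RPKM gave 0.196 for DNA repair and 0.116 for Wnt genes. Without 1 library, adjusted p values ran from 0.00605 to 0.119 for DNA repair, 0.00173 to 0.0849 for p53 targets, 0.0252 to 0.119 for H3K9 and heterochromatin genes and 0.022 to 0.13 for Wnt genes.

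Lists that camera did not call with all 4 libraries passed in some fits without 1 library. The ranges of adjusted p were 0.044 to 0.175 for activation and commitment, 0.0118 to 0.951 for histones, 2.92e-05 to 0.951 for endothelial, 0.0445 to 0.877 for fibro-adipogenic, 0.0206 to 0.957 for Schwann cell and 0.000735 to 0.861 for tenocyte markers, and 0.0464 to 0.861 for mitochondrially encoded genes. Lists never called also changed direction, with ranges without 1 library of 0.502 to 0.951 for immune, 0.0536 to 0.555 for smooth muscle, 0.465 to 0.951 for Notch and 0.341 to 0.951 for senescence genes. Other changes of direction, none called, were those of immune markers under scaling by reads listed (0.484), the filter on CPM (0.834) and the filter on mean RPKM (0.71), of Schwann cell markers under scaling by reads listed (0.903), of histones under the filter on CPM (0.823), and of smooth muscle markers under the filter on CPM (0.992), the filter on mean RPKM (0.967), limma-voom (0.905) and the replicate block (0.896). Genes named as abundant list members with small differences changed sign, none of them called. Scaling by reads listed moved the median over all genes by -0.20, so sign changes of genes near 0 follow from the scaling itself and say nothing about these genes. It gave log2 fold changes of -0.23 for Atp5b, -0.13 for Brdt, -0.17 for Ctnnb1, -0.0832 for Fabp4, -0.00855 for Heyl, -0.17 for Hist1h2bc, -0.0240 for Jmjd1c and -0.23 for Lmna. Without 1 library, log2 fold changes ran from -0.0461 to 0.0177 for Atp5a1, -0.0364 to 0.0598 for Atp5b, -0.0923 to 0.159 for Brdt, -0.0192 to 0.574 for Egr2, -0.33 to 0.63 for Fabp4, -1.03 to 0.0394 for Fmod, -2.01 to 1.85 for Hba-a2, -1.54 to 2.07 for Hbb-bs, -0.14 to 0.60 for Heyl, -1.11 to 0.0618 for Hist1h1c, -0.20 to 0.325 for Hist1h2bc, -0.0534 to 0.0672 for Lmna, -0.0686 to 0.0423 for Notch3, -0.134 to 0.0122 for Piwil4, -0.24 to 0.14 for Plvap, -1.05 to 0.0293 for Thbs4 and -1.11 to 0.0621 for Tpm1. The cause of these ranges was not tested. Of the 67 named genes other than Hr, 10 more passed with limma-voom and 28 more with the replicate block. Depth limits genes with few reads, such as Piwil4, more than the abundant ones.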

Other observations

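The imprinted, tubulin, acetylcholine receptor, adult fast-fibre and early differentiation groups and the single genes of the next paragraph were chosen after the values were seen, and so were all tests in this part, so their results describe these 4 libraries and are not independent evidence.

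Several imprinted genes stood among those with the clearest separation. Of 32 measured imprinted genes, 6 were lower and 2 higher when adjusted over the list alone, 0 passed limma over all genes, and the authors' deposited table had 4 lower and 3 higher. The list had a camera adjusted p of 0.0381, over the 5 lists written after the values were seen, or an adjusted p of 0.347 with an estimated correlation. Those lower were Cdkn1c, Dlk1, Meg3, Mest, the zinc-finger gene Plagl1 (19.3 and 19.5 RPKM in control, 13.0 and 10.8 RPKM in knockout) and the adaptor gene Grb10 (35.5 and 35.3 RPKM, 23.0 and 25.4 RPKM), and those higher were Asb4 and Dio3. Dlk1, Meg3 and Dio3 belong to 1 imprinted cluster, in which Dio3 was higher and Mirg, which lies between Meg3 and Dio3, had a log2 fold change of -0.10. Most tubulin genes were higher. Of 14 measured tubulins and gamma-tubulin complex genes, 0 passed limma over all genes, and 9 were higher and 0 lower when adjusted over the list alone, including Tubb4a and Tubb2a besides Tuba4a and Tuba1c, and 8 were higher in the authors' deposited table. Mzt1 (25.6 and 21.2 RPKM, 19.4 and 18.1 RPKM) and Tubb5 (22.1 and 22.8 RPKM, 22.0 and 20.1 RPKM) went the other way. The list had an adjusted p of 1.24e-06 with camera and an adjusted p of 0.166 with an estimated correlation. Of 9 measured acetylcholine receptor and synapse genes, 0 passed limma over all genes, and 4 were lower and 0 higher when adjusted over the list alone. The list had a camera adjusted p of 0.00572, or an adjusted p of 0.347 with an estimated correlation. The receptor subunit gene Chrnd had 3.24 and 6.43 RPKM against 0.671 and 0.722 RPKM, with a limma adjusted p of 0.133 over all genes, whereas Chrnb1 had a log2 fold change of 0.03. Among the most abundant transcripts, the metallothioneins Mt1 (4390 and 4768 RPKM, 10288 and 16543 RPKM) and Mt2 (4624 and 3785 RPKM, 9053 and 11863 RPKM) and the neuropeptide gene Gal (4752 and 2479 RPKM, 8678 and 11831 RPKM) were higher in both knockout libraries, with limma adjusted p values of 0.153, 0.153 and 0.177. Cyp26a1, which degrades retinoic acid, had 4.18 and 1.13 RPKM against 19.5 and 11.8 RPKM. Gm12603 had an adjusted p of 3.7e-06 in the authors' deposited table but was listed at 0 in every library except control 2, where it had 2.27 RPKM.

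Lower myofibre genes may come in part from fibre RNA in 1 control library. Over the fixed list of 25 myofibre genes the median log2 fold change was -0.84 against both controls, while the median difference of the knockout mean was -1.36 from control 2 and -0.40 from control 1. The latter had a standard error of 0.79 with the correlation of 0.678 estimated between these genes (0.19 if they were independent). It therefore decides nothing about control 2 for the list, and fibre RNA in control 2 stays open as a source. Both control values lay above both knockout values in 17 of the 25 members and below them in 1. Actc1 had 59.9 RPKM in control 1 against 5.60 and 9.22 RPKM in knockout, so control 2 alone does not give the difference of every member. A first run used fixed cutoffs for these differences and tested a list of 16 early differentiation genes, which lay -1.217 from control 1. That list had been chosen from genes seen to be lower, so it was replaced by the fixed myofibre list, and the bound of 2 standard errors, also used for the cell cycle genes, and the use of the correlation were set after that run. A test on adult fast-fibre genes alone was dropped for the same reason. A loss of differentiating cells with the genotype stays open and was not tested beyond these values.

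Cell cycle genes had a negative median against either control library. The median difference of the knockout mean over the 36 genes was -0.61 from control 1 and -0.75 from control 2. Against both controls the median was -0.60, so leaving out control 2 did not shrink it, as cycling cells in control 2 alone would require. Both knockout values lay below both control values in 26 of the 36 members and above them in 4. The difference from control 1 had a standard error of 0.35 with the correlation of 0.195 estimated between these genes (0.12 if they were independent). Less than 2 of the wider standard error part it from 0. Cycling cells in control 2 alone, a candidate source, are thus not excluded, but these values do not point to them. Other cell types in the control libraries are another candidate source, although the sort removes CD31, CD45 and Sca1 positive cells. The 49 endothelial, immune and fibro-adipogenic markers together had a median of -0.0734, against -0.60 for the cell cycle list. Its standard error was 0.12 if the genes were independent. The correlations estimated within these lists were 0.743, 0.0117 and 0.111, in the same order, so that error may be too narrow. These markers went both ways, with 4 fibro-adipogenic markers lower and 2 higher when adjusted over the list alone and 4 lower and 0 higher in the authors' deposited table, so this source stays open. The 2 most abundant cell cycle members, Pcna and Rrm2, were higher in the knockout. A difference in cycling with the genotype and a difference in how the groups of cells were prepared were not tested.

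Ribosomal protein and respiratory chain genes are short and abundant, and trends with gene length and expression may account for their higher values. Among 10000 random lists matched on gene length alone, drawn from genes outside the family, the ribosomal protein median of 0.47 stood at percentile 100, above the central 95% from 0.0193 to 0.28. The random lists do not share the correlation of 0.795 estimated between ribosomal protein genes. Their central 95% is thus too narrow for such a family, and the percentile cannot decide whether length alone is enough. The respiratory chain median of 0.16 stood at percentile 64.9 of its lists, within 0.00773 to 0.27. Among lists matched on both length and expression, the ribosomal protein median stood at percentile 94.2, within 0.23 to 0.49, and the respiratory chain median at percentile 6.58, within 0.14 to 0.37. The ribosomal protein median was thus higher than most of its matched lists without leaving their central 95%, and the respiratory chain median was lower than most. Leaving the family out was a restriction added after a first run that left no family out, with the same outcome for the lists matched on both. Whether these trends came from the library preparation, the RNA or the genotype was not tested, since each group holds only 2 libraries.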
